A study of Homo sapiens with 8 samples.

How the data were processed

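Total RNA of U87 cells was extracted with the Roche High Pure kit, and stranded libraries were made with a TruSeq total RNA kit from Illumina after Ribo-Zero Gold depletion, per the labels' protocols. The cells were grown in DMEM that held serum (10%) and antibiotics (1%), per the labels' protocols. Reads were trimmed with cutadapt 1.16, aligned with STAR 2.7.0 to GRCh38 and counted per gene with featureCounts 1.6.3 of the Subread package, per the submitters' processing notes. The deposited values are raw read counts per gene from this counting, per the submitters' processing notes, and no normalization is recorded for them. The annotation release and the strand setting of the counting are not given in the sources used here, nor are the dose and duration of AsiDNA. Antisense and overlapping genes are therefore uncertain.

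The table held 58884 Ensembl gene identifiers and 8 columns, all of which were mapped to a group. A name was found for 58876 identifiers. The 8 others held 0.0029% of the counts. No count in any library was found for 28036 identifiers. The libraries were put in 4 groups of 2 by their labels: DMSO, AsiDNA, belinostat, and AsiDNA with belinostat. Library sizes lay between 6057394 and 9699637 counts, where 3 counts equal between 0.292 and 0.508 CPM.

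All statistics were computed here from the deposited counts in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 14741, and libraries were scaled with TMM factors. All 8 libraries were fitted together with 1 coefficient per group, which left 4 residual degrees of freedom, a prior of 9.56 and a common dispersion of 0.014. The 5 comparisons between groups and the interaction were tested with edgeR's quasi-likelihood F-test, and p-values were adjusted with the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of F. Log2 CPM values used a prior count of 2. Ratios of genes with 3 counts or fewer in a group are given with exact intervals for counting error.

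Gene lists were compared with all other genes by camera of limma 3.58.1, with its preset correlation of 0.01 between genes, and adjusted over the 46 lists with at least 5 tested genes, of 48 lists set beforehand. The same test was also run with the correlation estimated from the data, and as a rotation test (fry). Members of a list were also adjusted over the list alone.

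The genes named in the text were chosen by a rule: the 8 largest rises and falls for belinostat or AsiDNA against DMSO and the 5 largest in the other comparisons, among called genes with a name, a mean log2 CPM of at least 2 and both libraries of 1 group beyond both of the other. Up to 4 members with the smallest adjusted p were named for each list described, and some genes were named throughout, among them HDAC1, HDAC2, HDAC3, HDAC6, PRKDC, XRCC5, XRCC6, PARP1, BRCA1 and CDKN1A. Results for a few genes that the rule names are not reported here. MALAT1, NEAT1 and SNORD3A were chosen after their values were seen.

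The grouping, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were set before the data were examined. These alternatives were RLE factors, scaling by library size only, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 2 libraries, only the groups compared, a replicate block, an adjusted p under 0.01, a 2-fold limit, a test against a 1.5-fold change (glmTreat) and leaving out each library. The other 4 were chosen after seeing the data: a model term for the log2 share of counts on sense-intronic genes, camera with that term, a fit without the 10 most abundant genes, and a fit of protein-coding genes only. For the AsiDNA and belinostat effects, which share the DMSO controls, 20 data sets without group differences were simulated for comparison.

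The steps were tested on simulated data with 14197 tested genes, of which 200 were changed by belinostat. Of the 2-fold changes 85% were called and of the 4-fold changes 100%, with median fitted log2 fold changes of 1.01 and 2.01. Of 13997 unchanged genes 10 were called. The AsiDNA comparison, with no simulated change, gave 1 call. The changes were simulated in the belinostat group and not in the combination, so the 200 genes also differ in the interaction, which gave 157 calls. Camera, run on a list of 30 raised genes and a random list of 30, separated them (2.14e-85 against 0.655). These simulated data drew each gene independently and lack the coordinated difference between the DMSO replicates. The rates of calls and the camera result therefore need not hold for the real libraries.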

Results

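Total RNA from U87 cells, an established human glioblastoma line, was sequenced after depletion of ribosomal RNA. The 8 libraries fell into 4 groups of 2: cells given the solvent DMSO, cells kept long-term on AsiDNA, cells given 1 µM belinostat for 24 h, and AsiDNA cells given the same belinostat treatment. AsiDNA is a short double-stranded oligonucleotide that mimics a DNA break and acts as a decoy for repair enzymes, and belinostat is an inhibitor of histone deacetylases. The libraries held between 6057394 and 9699637 counts, so that 3 counts corresponded to 0.292 to 0.508 CPM. The labels do not say whether the replicates came from separate cultures, and p-values therefore measure only the spread between these samples, which may be technical. Of 58884 genes in the table, 14741 had enough counts to be tested. Log2 fold changes are given ± the standard error and CPM values ± the SD of n = 2 libraries. Intervals and floors cover counting error only.

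Belinostat separated the groups most. The first principal component of log2 CPM held 65.6% of the variance and placed the belinostat libraries at 84.8 and 82.1, the combination libraries at 35.0 and 26.9, and the DMSO and AsiDNA libraries between -65.5 and -36.9. The second component held 22.1% and placed DMSO replicate 2 at 52.4, while DMSO replicate 1 lay at 2.7 and the AsiDNA libraries at -3.93 and -4.33. The DMSO replicates also differed most from each other: 11.1% of 8142 genes with a mean log2 CPM above 4 differed by more than 1.5-fold, against 0.184% in AsiDNA, 0.786% in belinostat and 0.540% in the combination.

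MALAT1 and NEAT1, long noncoding RNAs that are retained in the nucleus, were highest in the belinostat libraries. They were singled out after their values were seen. Together they took 1.86% ± 1.35 of all counts in DMSO (SD, n = 2), 0.720% ± 0.046 in AsiDNA, 12.8% ± 0.862 in belinostat and 2.59% ± 0.748 in the combination. Within DMSO the share was 0.911% in replicate 1 and 2.82% in replicate 2, the latter above the 2.06% of combination replicate 2. MALAT1 (ENSG00000251562, chromosome 11, 65497688 to 65506516, GRCh38) rose by 3.17 ± 0.32 on the log2 scale with belinostat against DMSO (adjusted p = 2.96e-06) and by 2.18 ± 0.31 in the combination against AsiDNA (adjusted p = 8.81e-05). NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65445540) rose by 2.65 ± 0.43 and 1.65 ± 0.42 in these comparisons (adjusted p = 0.000163 and 0.00588). In the combination against DMSO, MALAT1 rose by 1.07 ± 0.30 (adjusted p = 0.0097) and NEAT1 was at 0.14 ± 0.41 (adjusted p = 0.798). NEAT1 took 0.361% of counts in DMSO replicate 1 and 1.438% in DMSO replicate 2, against 1.055% and 0.641% in the combination libraries. Its direction therefore depends on which DMSO library is compared. Genes annotated as sense-intronic, whose reads lie in introns of other genes, held 0.085% of counts in DMSO, 0.0535% in AsiDNA, 0.135% in belinostat and 0.05% in the combination. This share was 0.057% in DMSO replicate 1 and 0.113% in DMSO replicate 2.

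**Figure D1:**
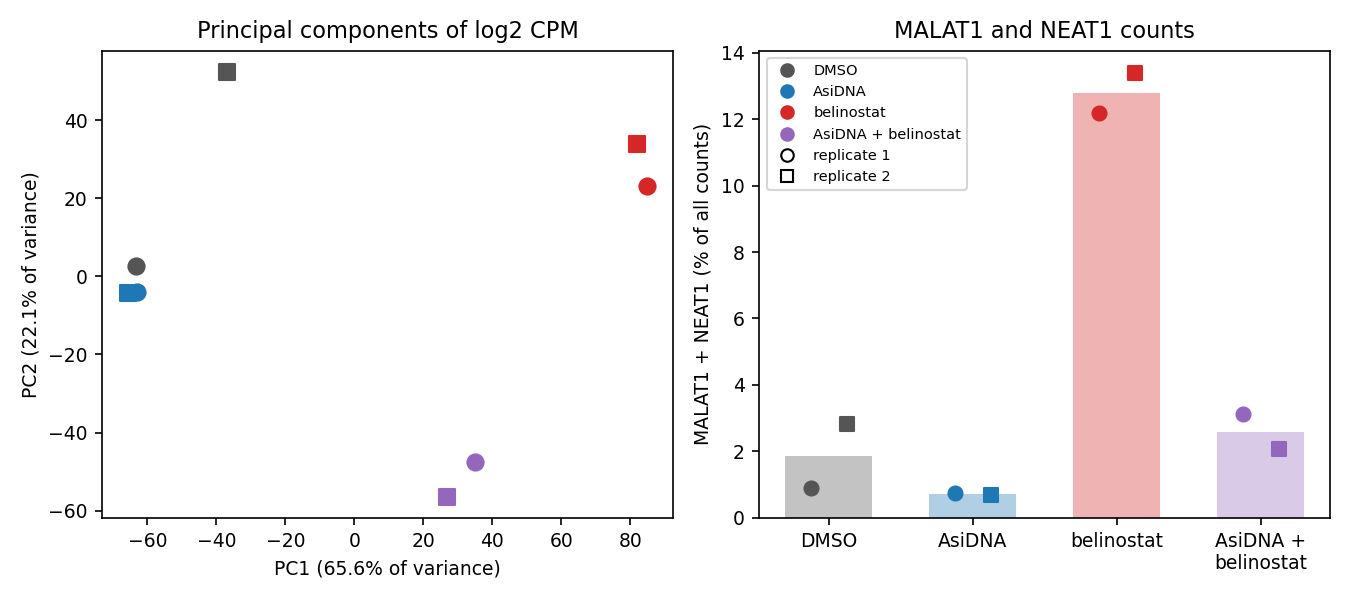
Left, the first and second principal components of log2 CPM for the 8 libraries, in arbitrary units; DMSO replicate 2 lies at 52.4 on the second component and DMSO replicate 1 at 2.7. Right, the percent of all counts on MALAT1 and NEAT1, with bars for the mean of each group and points for the libraries; the belinostat libraries reach 12.2% and 13.4%, the other libraries at most 3.12%.

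The comparison of belinostat with DMSO asks what 24 h of histone deacetylase inhibition changed in cells not kept on AsiDNA. LOXL4, a lysyl oxidase that crosslinks matrix proteins (ENSG00000138131, chromosome 10, 98247690 to 98268250), rose from 0.696 ± 0.16 to 116 ± 2.5 CPM, a log2 fold change of 7.36 ± 0.25 (adjusted p = 8.24e-10). HAS2, which makes hyaluronan (ENSG00000170961, chromosome 8, 121612116 to 121641390), fell from 206 ± 40 to 5.30 ± 1.4 CPM, a log2 fold change of -5.31 ± 0.23 (adjusted p = 3.82e-09). The dehydrogenase gene DHRS2 rose from 1.48 ± 0.52 to 75.7 ± 18 CPM, and the homeobox gene PRRX1 fell from 109 ± 15 to 5.53 ± 1.5 CPM. In all, 4395 genes were higher and 4071 lower at an adjusted p under 0.05, of which 2578 and 1892 differed by at least 2-fold.

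DNAI1, which encodes a dynein chain of cilia, gave 2 counts in DMSO and 507 with belinostat, a ratio of 354 (95% interval 97.6 to 2930). GPRIN3 gave 3 and 121 counts, a ratio of 56.4 (18.8 to 277). Among the genes with the largest rises were also the WNT regulator DACT3 (6.53 ± 0.46), LIVAR (6.41 ± 0.43), the corepressor gene HR (5.84 ± 0.54) and the synaptic vesicle gene UNC13A (5.84 ± 0.39). FAR2, a fatty acyl-CoA reductase, fell by 4.63 ± 0.41. The other large falls under the rule for named genes were of replication-dependent histone genes: H2AC4 (-4.98 ± 0.53), H3C12 (-4.70 ± 0.48), H2BC11 (-4.57 ± 0.35), H2BC17 (-4.36 ± 0.27) and H2AC12 (-4.34 ± 0.29). Adjusted p lay between 5.95e-08 and 4.31e-06 for these histone genes. The histone genes are near-identical copies, so the value of any single member is uncertain.

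As a list, 52 of 55 measured replication-dependent histone genes fell and none rose, with a median log2 fold change of -3.08. Adjusted over the list alone, the count was also 52. H2AC11 fell by 3.69 ± 0.24 and H2AC16 by 3.73 ± 0.26. In camera, which compares a list with all other genes, the list was lower with an adjusted p of 7.79e-36 (adjusted p = 0.39 with an estimated correlation). The histone genes held 0.447% of counts in DMSO replicate 1 and 0.267% in DMSO replicate 2, against 0.050% and 0.048% in the belinostat libraries. Without DMSO replicate 1 the median was -2.50, and without DMSO replicate 2 it was -3.44.

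Cell cycle genes fell together. Of 40 genes of G2 and mitosis 39 fell, also when adjusted over the list alone, with a median of -1.62 and a camera adjusted p of 1.78e-31 (adjusted p = 0.255 with an estimated correlation). They included the mitotic cyclin CCNB1 (-2.55 ± 0.16), the kinesin KIF20A (-2.32 ± 0.15), the proliferation marker MKI67 (-2.10 ± 0.13) and the kinase CDK1 (-1.64 ± 0.12). Of 38 DNA replication genes 36 fell, 36 also when adjusted over the list alone, with a median of -1.45 and a camera adjusted p of 5.82e-21 (adjusted p = 0.255 with an estimated correlation). Thymidylate synthase TYMS fell by 2.7 ± 0.19, the ribonucleotide reductase subunit RRM2 by 2.49 ± 0.16, UHRF1 by 2.30 ± 0.13 and MCM10 by 1.94 ± 0.14.

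Genes of several DNA repair pathways were lower with belinostat. Nucleotide excision repair was an exception, with 8 of 20 genes higher and 7 lower, the same over the list alone (median 0.23, camera adjusted p = 0.675). Its median was 0.14 without DMSO replicate 1 and without DMSO replicate 2, and 0.13 with the sense-intronic share as a model term, where 7 were higher and 3 lower. The homologous recombination list had 20 of 29 genes lower and 2 higher, the same numbers when adjusted over the list alone (camera adjusted p = 0.000144; adjusted p = 0.39 with an estimated correlation). In it BRCA1 fell by 1.56 ± 0.12 (adjusted p = 3.3e-07), NBN by 1.45 ± 0.15, BARD1 by 1.40 ± 0.13 and RBBP8 by 1.24 ± 0.13. In base excision and single-strand break repair 15 of 23 genes were lower and 1 higher, 16 and 1 adjusted over the list alone (camera adjusted p = 0.00168; adjusted p = 0.39 with an estimated correlation), among them FEN1 (-1.61 ± 0.15), NEIL3 (-1.59 ± 0.18) and the poly(ADP-ribose) polymerase PARP1 (-1.30 ± 0.15, adjusted p = 8.11e-06). In mismatch repair 10 of 14 were lower, 10 also over the list alone (camera adjusted p = 0.000821, and adjusted p = 0.342 with an estimated correlation). The sliding clamp gene PCNA was at -1.81 ± 0.14 and RFC3 at -1.46 ± 0.13. Both genes also belong to the DNA replication list, so these lists overlap. The Fanconi anemia list had 13 of 22 lower and 3 higher, the same over the list alone (camera adjusted p = 0.0115; adjusted p = 0.305 with an estimated correlation), with USP1 at -1.72 ± 0.14 and FANCI at -1.42 ± 0.13.

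Checkpoint genes had 13 of 21 members lower and 4 higher, 14 and 4 adjusted over the list alone (camera adjusted p = 0.000766; adjusted p = 0.255 with an estimated correlation). TIMELESS, a replication fork protein, fell by 3.26 ± 0.17, CLSPN by 2.71 ± 0.14, the histone variant gene H2AX by 2.20 ± 0.21 and the phosphatase CDC25A by 2.12 ± 0.17. The end-joining list did not pass (camera adjusted p = 0.234), with 8 of 18 members lower and 3 higher, the same numbers over the list alone. Its Ku subunits XRCC5 and XRCC6 fell by 1.17 ± 0.15 and 0.93 ± 0.16 (adjusted p = 2.62e-05 and 0.00025), the kinase PRKDC by 0.54 ± 0.14 (0.00464) and SHLD2 by 2.17 ± 0.17, whereas TP53BP1 rose by 1.09 ± 0.11. The p53 target list did not pass either (camera adjusted p = 0.234), with 12 of 31 members lower and 8 higher, also over the list alone. With the sense-intronic share as a model term 6 were lower and 5 higher, and the median went from -0.38 to -0.05. The cell cycle inhibitor CDKN1A fell by 1.27 ± 0.14 (adjusted p = 7.8e-06), AEN by 1.84 ± 0.13 and MDM2 by 1.46 ± 0.14, and CYFIP2 rose by 1.49 ± 0.15.

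Among the deacetylases themselves, HDAC3 rose by 1.61 ± 0.12, from 66.6 ± 2.7 to 203 ± 18 CPM (adjusted p = 2.9e-07), and HDAC6 rose by 0.64 ± 0.14 (0.00197). HDAC1 was at 0.02 ± 0.12 (adjusted p = 0.918) and HDAC2 at -0.12 ± 0.13 (0.454). In the list of deacetylases and sirtuins 7 of 17 members were higher and 3 lower, the same numbers over the list alone (camera adjusted p = 0.201), with HDAC5 at 1.39 ± 0.15, SIRT7 at 1.24 ± 0.16 and SIRT1 at -1.44 ± 0.21. DHRS2 belongs to a list of genes known to respond to deacetylase inhibitors, of which 9 of 18 rose and 7 fell, also over the list alone (camera adjusted p = 0.075, and 0.0125 with the sense-intronic share as a model term). Those that fell included the histone gene H2BC12 (-3.09 ± 0.24) and CDKN1A, whose fall is given with the p53 targets.

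Neuronal genes with enough counts rose: 13 of 17 measured members were higher and 1 lower, the same over the list alone, with a median of 1.40 and a camera adjusted p of 2.17e-05 (adjusted p = 0.255 with an estimated correlation). The list holds 46 genes with a median of 0.185 CPM, of which only these 17 were tested. A gene can pass the filter through 1 group alone, so the tested members may favor genes that belinostat raises. The synaptic vesicle protein gene SYP rose by 5.18 ± 0.20, the microtubule protein gene MAP2 by 2.61 ± 0.23, BEX1 by 2.39 ± 0.15 and the vesicle fusion gene SNAP25 by 1.40 ± 0.18. Lists of glial markers did not pass. Of 9 astrocyte markers 6 were higher, also over the list alone (median 0.77, camera adjusted p = 0.0549, and 0.0254 with the sense-intronic share as a model term). Of 6 oligodendrocyte lineage markers 4 were lower, also over the list alone (median -1.08, camera adjusted p = 0.0549). Of 7 metallothionein-list genes 5 rose and 1 fell, also over the list alone, with a camera adjusted p of 0.0115 (adjusted p = 0.478 with an estimated correlation). MT1X rose by 3.44 ± 0.19, MT3 by 2.17 ± 0.27 and MT1E by 1.66 ± 0.20. Metallothionein genes are close copies of each other, so the split between them is uncertain.

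Genes for building ribosomes fell, with 23 of 31 members of the ribosome biogenesis and MYC target list lower and 1 higher, 24 and 1 over the list alone (camera adjusted p = 1.74e-06; adjusted p = 0.255 with an estimated correlation). Nucleolin NCL fell by 2.27 ± 0.14, the spermidine synthase SRM by 1.87 ± 0.19 and UTP20 by 1.51 ± 0.14. Of 38 ribosomal protein genes 27 fell, also over the list alone, with a median of -0.57 and a camera adjusted p of 0.000112 (adjusted p = 0.659 with an estimated correlation), for example RPS2 (-1.06 ± 0.15) and RPS19 (-1.02 ± 0.13). The ribosomal protein count was 25 without DMSO replicate 1 and 37 without DMSO replicate 2, and pseudogenes can take some of the reads of these genes. Anti-apoptotic genes had 7 of 10 members lower and 1 higher, also over the list alone (camera adjusted p = 0.00806; adjusted p = 0.478 with an estimated correlation), among them BIRC5 (-2.58 ± 0.21) and the caspase inhibitor XIAP (-1.65 ± 0.15). Heat shock proteins had 12 of 15 lower and 1 higher, 13 and 1 over the list alone (camera adjusted p = 0.000766; adjusted p = 0.557 with an estimated correlation), with FKBP4 at -1.50 ± 0.14 and HSPD1 at -1.47 ± 0.15. With the sense-intronic share of each library as a model term, 7 of the heat shock genes were lower. Of the ribosomal protein genes 22 were then lower and 1 higher (median -0.34, camera adjusted p = 0.0118).

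Genes acting on the extracellular matrix moved in both directions. In the matrix list 13 of 27 were lower and 5 higher, 15 and 5 over the list alone (camera adjusted p = 0.0415; adjusted p = 0.478 with an estimated correlation and 0.0542 with the sense-intronic share as a model term): fibrillin FBN1 fell by 2.33 ± 0.13 and the collagen chaperone SERPINH1 by 2.10 ± 0.15, while COL3A1 rose by 2.03 ± 0.26 and fibronectin FN1 by 1.17 ± 0.17. In the list of matrix proteases and their inhibitors 9 of 22 were lower and 7 higher, also over the list alone (camera adjusted p = 0.0168; adjusted p = 0.557 with an estimated correlation and 0.0551 with the sense-intronic share as a model term). ADAMTS1 fell by 2.90 ± 0.14, the urokinase receptor PLAUR by 2.23 ± 0.15, MMP14 by 2.13 ± 0.13 and urokinase PLAU by 1.85 ± 0.13. The intermediate filament gene NES rose by 2.60 ± 0.21 and NOTCH1 fell by 1.52 ± 0.13 within a stem cell marker list that did not pass (7 of 16 lower and 3 higher, also over the list alone; camera adjusted p = 0.234). Of the 46 lists tested, 18 passed camera and 0 passed with an estimated correlation, where the lowest adjusted p was 0.255. The rotation test (fry), which does not compare a list with all other genes, passed 34. In the combination fry passed 29 lists against DMSO, 30 against AsiDNA and 28 against belinostat.

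The combination against AsiDNA alone asks what belinostat changed in cells kept on AsiDNA. LOXL4 rose by 8.52 ± 0.28 (adjusted p = 8.75e-10), VSIR, an immune checkpoint gene, by 6.84 ± 0.31 (9.82e-09), while FAR2 (-3.94 ± 0.36), PLEKHG4B (-3.91 ± 0.20) and HAS2 (-3.65 ± 0.20) fell. UNC13A gave 2 counts in AsiDNA and 334 in the combination, a ratio of 183 (95% interval 50.4 to 1520), and the adhesion gene CADM3 gave 1 and 118, a ratio of 130 (22.8 to 5160). TMEM63C had 0 counts in both AsiDNA libraries and 59 in the combination, at least 21.6-fold higher against a floor of 3 counts over the group. SMAGP fell by 3.59 ± 0.37, and so did RPSAP52 by 3.73 ± 0.21, a pseudogene transcript whose reads may be shared with its parent gene. In total 3199 genes were higher and 3120 lower, of which 1462 and 1310 by at least 2-fold; without AsiDNA replicate 1 the total was 4102 and without AsiDNA replicate 2 it was 4198, instead of 6319.

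In AsiDNA cells belinostat again lowered the cell cycle lists. All 40 genes of G2 and mitosis fell, also over the list alone (median -1.43, camera adjusted p = 2.1e-37; adjusted p = 0.147 with an estimated correlation), with KIF20A at -2.23 ± 0.14, CCNB1 at -2.14 ± 0.15 and MKI67 at -1.83 ± 0.13. Of the DNA replication genes 33 of 38 fell, 34 lower and 1 higher over the list alone (camera adjusted p = 1.64e-15; adjusted p = 0.144 with an estimated correlation), with UHRF1 at -2.01 ± 0.13, TYMS at -1.98 ± 0.18 and RRM2 at -1.73 ± 0.15. Of the histone genes 49 of 55 fell, 51 lower and 1 higher over the list alone (median -1.63, camera adjusted p = 8.84e-20; adjusted p = 0.375 with an estimated correlation), with H2BC11 at -2.77 ± 0.28, H2BC14 at -2.47 ± 0.25 and H2BC17 at -2.14 ± 0.21. The homologous recombination list had 22 of 29 genes lower, 23 over the list alone (camera adjusted p = 3.89e-07; adjusted p = 0.241 with an estimated correlation), among them BRCA1 (-1.20, adjusted p = 5e-06) and the nuclease DNA2 (-1.61 ± 0.18). Checkpoint genes had 13 of 21 lower and 1 higher, 14 and 1 over the list alone (camera adjusted p = 8.2e-05; adjusted p = 0.144 with an estimated correlation), with TIMELESS at -2.75 ± 0.17 and CLSPN at -2.29 ± 0.14.

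HDAC3 rose by 1.36 ± 0.12 (adjusted p = 2.1e-06) in AsiDNA cells. PARP1 fell by 0.71 (adjusted p = 0.0015), XRCC5 by 0.62 (0.00461) and CDKN1A by 0.55 (0.00654), whereas PRKDC was at -0.24 (0.191), XRCC6 at -0.30 (0.137) and HDAC1 at -0.29 (0.0741). The neuronal list had 12 of 17 members higher, 13 higher and 1 lower over the list alone (camera adjusted p = 2.75e-07; adjusted p = 0.144 with an estimated correlation), with SYP at 5.72 ± 0.21, BEX1 at 2.42 ± 0.15 and MAP2 at 2.32 ± 0.24. Hypoxia and glycolysis genes had 19 of 32 higher and 3 lower, 20 and 3 over the list alone (camera adjusted p = 8.2e-05; adjusted p = 0.375 with an estimated correlation), for example NDRG1 (1.71 ± 0.15), ADM (1.12 ± 0.12) and the glucose transporter SLC2A3 (1.12 ± 0.13). Autophagy and lysosome genes had 20 of 27 higher and 1 lower, 21 and 1 over the list alone (camera adjusted p = 0.000252; adjusted p = 0.375 with an estimated correlation), among them the autophagy kinase ULK1 (1.17 ± 0.16), ATP6V0D1 (1.07 ± 0.16) and ATG9A (0.88 ± 0.13). Mitochondrially encoded genes had 13 of 15 higher, 15 over the list alone (camera adjusted p = 0.0145; adjusted p = 0.602 with an estimated correlation), with MT-ND5 at 0.87 ± 0.21 and MT-CYB at 0.69 ± 0.18. Mitochondrially encoded genes held 1.157% of counts in combination replicate 1 and 0.815% in combination replicate 2, against 0.73% and 0.716% in the AsiDNA libraries. The ribosomal protein list had 2 of 38 members higher and none lower, 0 over the list alone (camera adjusted p = 0.866), and its median of 0.06 turned to -0.07 when libraries were scaled by size only. Without DMSO replicate 1 or without DMSO replicate 2, 6 were higher and 6 lower, and with the sense-intronic share as a model term 6 were higher and 7 lower.

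Across the 14741 genes, the belinostat effects in the 2 backgrounds, which share no library, correlated with r = 0.809. The slope of the effect in AsiDNA cells on the effect against DMSO was 0.691. Both values describe genes, which are not independent replicates. Error in the effect against DMSO, which includes the difference between the DMSO replicates, lowers the slope, so it alone does not show a weaker response. Genes called higher in both numbered 2471, against 953.8 for independent lists, genes called lower in both 2601 against 861.6, and 27 were called in opposite directions against 1813.7. Over leave-one-out fits r lay between 0.679 and 0.783. Scaling by library size only moved the median log2 fold change over all genes from 0.061 to -0.076 for belinostat against DMSO, from 0.015 to -0.118 for the combination against AsiDNA and from -0.013 to -0.204 for the combination against DMSO; the fold changes given here are relative to TMM scaling.

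**Figure D2:**
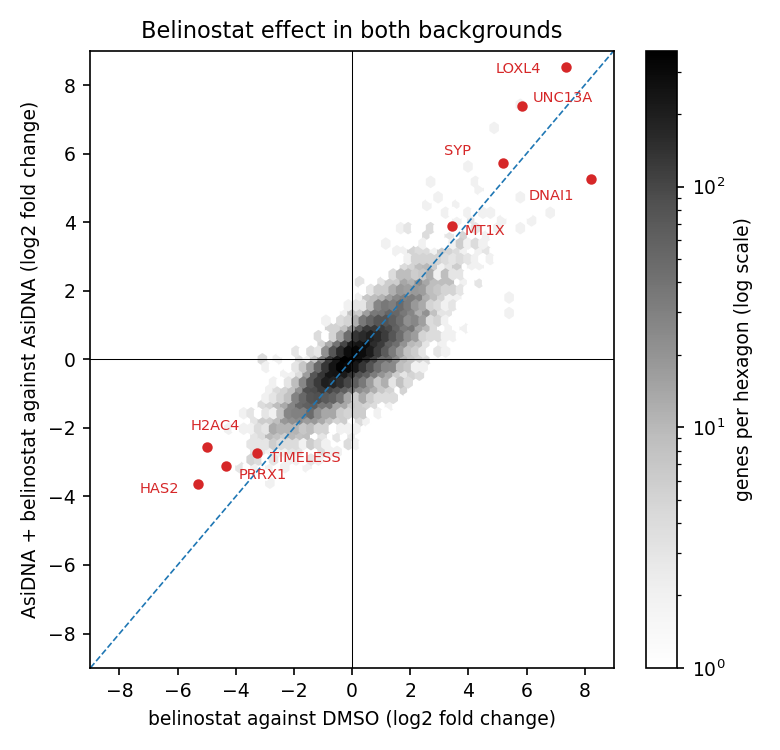
Log2 fold changes of 14741 genes with belinostat against DMSO (x axis) and with the combination against AsiDNA (y axis), shaded by the number of genes per hexagon, with named genes in red and a dashed line where both are equal. The values correlate with r = 0.809, and LOXL4 lies at 7.36 and 8.52.

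The comparison of AsiDNA with DMSO asks what long-term AsiDNA changed without belinostat. EGR1, an immediate early transcription factor (ENSG00000120738, chromosome 5, 138465490 to 138469315), fell from 245 ± 38 to 74.5 ± 35 CPM, a log2 fold change of -1.72 ± 0.24 (adjusted p = 0.0399). The matricellular genes CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373) and CCN1 (ENSG00000142871, chromosome 1, 85580761 to 85583962), both known YAP targets, fell from 33.3 ± 1.0 to 14.2 ± 1.1 CPM (-1.23 ± 0.15, adjusted p = 0.017) and from 51.2 ± 3.3 to 23.6 ± 0.21 CPM (-1.12 ± 0.16, adjusted p = 0.0455). These were the 3 genes called by edgeR's quasi-likelihood test, while 1674 genes had an unadjusted p under 0.05 and DESeq2 called 32. EGR1 was called in 3 of 8 fits that left out 1 library, CCN2 in 4 and CCN1 in 2, and none of them in a fit with only these 2 groups (adjusted p = 0.742, 0.72 and 0.72). Without DMSO replicate 1 the comparison gave 4955 genes, without DMSO replicate 2 it gave 62, and without any other single library 0 or 1.

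None of the DNA repair and deacetylase genes given here was called: PRKDC was at 0.08 (adjusted p = 0.828), XRCC5 at 0.27 (0.484), XRCC6 at 0.26 (0.513), PARP1 at 0.10 (0.79), BRCA1 at -0.12 (0.651), HDAC1 at 0.27 (0.421), HDAC3 at 0.13 (0.671) and CDKN1A at 0.14 (0.668). Of the 46 lists 11 passed camera, 0 passed with an estimated correlation (lowest adjusted p = 0.662) and 0 passed in fry. Replication-dependent histone genes were higher as a list (median 0.51, camera adjusted p = 9.78e-24; adjusted p = 0.662 with an estimated correlation), with 0 of 55 members called, also over the list alone. Without DMSO replicate 1, whose histone share was 0.447% against 0.267% in replicate 2, 52 of the 55 were higher (median 1.02). Without DMSO replicate 2 the number was 0 (median 0.16), and with the sense-intronic share as a model term it was also 0 (median 0.09, camera adjusted p = 0.00201). Ribosomal proteins were likewise higher as a list (median 0.23, camera adjusted p = 4.78e-08; adjusted p = 0.662 with an estimated correlation) with 0 of 38 members called, also over the list alone. Without DMSO replicate 1, 36 ribosomal protein genes were higher (median 0.43), without DMSO replicate 2 none was higher and 1 was lower (median 0.07), and with the sense-intronic share as a model term the list no longer passed (median 0.05, camera adjusted p = 0.227). The AP-1 and immediate early list was lower (camera adjusted p = 0.00201; adjusted p = 0.662 with an estimated correlation); EGR1 was its 1 called member, and over the list alone 7 were lower and 2 higher. Without DMSO replicate 1, 6 members of the AP-1 list were lower and 4 higher, and without DMSO replicate 2, 2 were lower. FOSB was at -1.33 ± 0.29 (adjusted p = 0.202) and NR4A1 at -1.57 ± 0.36 (0.243).

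**Figure D3:**
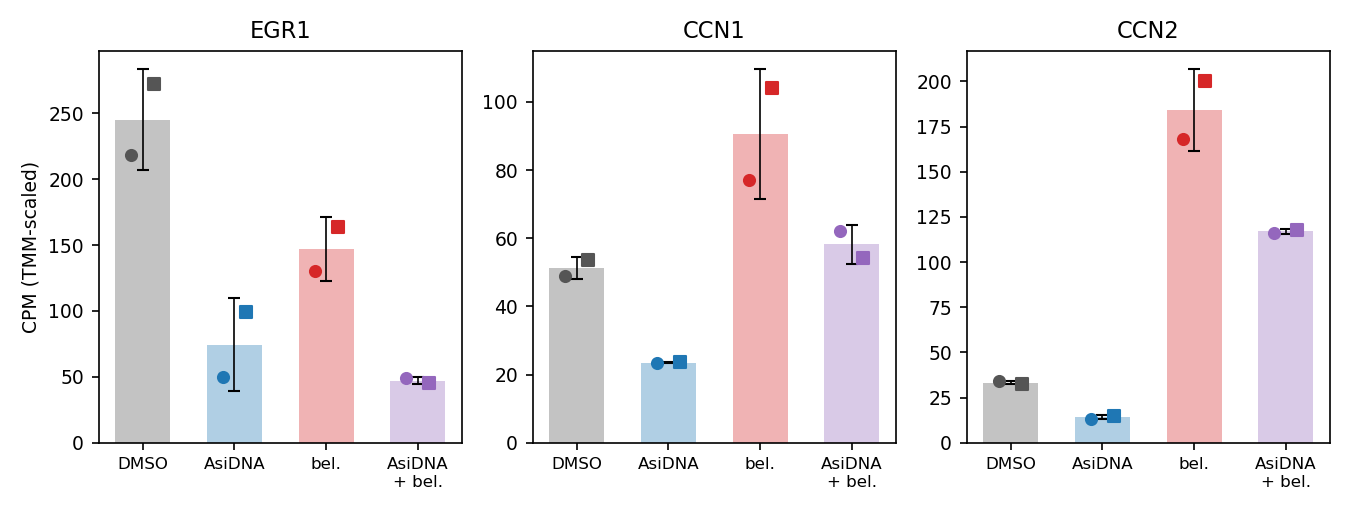
TMM-scaled CPM of EGR1, CCN1 and CCN2 in the 4 groups, with bars for the mean, error bars for the SD of n = 2 libraries and points for the libraries. CCN2 lies at 33.3 CPM in DMSO, 14.2 in AsiDNA, 184 in belinostat and 117 in the combination.

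The combination against belinostat alone asks what long-term AsiDNA changed under belinostat. Replication-dependent histone genes were higher in the combination: 52 of 55 rose, also over the list alone, with a median of 1.97 (camera adjusted p = 9.88e-38; adjusted p = 0.549 with an estimated correlation). H2AC4 rose by 3.33 ± 0.62 (adjusted p = 0.00126), H3C12 by 2.97 ± 0.53, H2AC12 by 2.81 ± 0.31, H2BC3 by 2.77 ± 0.45, H4C4 by 2.74 ± 0.31, H1-5 by 2.32 ± 0.25 and H4C5 by 2.12 ± 0.22. H2AC12, for example, lay at 3.28 ± 0.33 CPM in belinostat, 23.3 ± 0.96 in the combination and 99.4 ± 6.8 in AsiDNA. The nuclear RNAs went the other way, with MALAT1 falling by 2.10 ± 0.31 (adjusted p = 0.00045) and NEAT1 by 2.51 ± 0.43 (0.00083), but with the sense-intronic share as a model term MALAT1 was at -0.35 (adjusted p = 0.525) and NEAT1 turned to 0.15 (adjusted p = 0.856). In total 3237 genes were higher and 3161 lower, of which 597 and 1688 by at least 2-fold. The total of 6398 became 4220 without belinostat replicate 1, 3727 without belinostat replicate 2 and 3142 without combination replicate 2, and 85 with the sense-intronic share as a model term, where 1401 genes had an unadjusted p under 0.05.

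All 38 ribosomal protein genes rose, also over the list alone (median 0.80, camera adjusted p = 1.51e-19; adjusted p = 0.549 with an estimated correlation), such as RPLP2 (1.33 ± 0.17), RPS2 (1.32 ± 0.16) and RPS19 (1.10 ± 0.13). Oxidative stress genes had 17 of 22 higher, also over the list alone (camera adjusted p = 7.88e-10; adjusted p = 0.549 with an estimated correlation), with the ferritin chain FTL at 1.49 ± 0.19, the glutathione peroxidase GPX1 at 1.47 ± 0.18 and TALDO1 at 1.09 ± 0.14. DNA replication genes had 22 of 38 higher, 24 higher and 1 lower over the list alone (camera adjusted p = 3.61e-05; adjusted p = 0.549 with an estimated correlation), for example the thymidine kinase TK1 (1.30 ± 0.17) and MCM2 (1.08 ± 0.13). Mitochondrially encoded genes had 9 of 15 higher, also over the list alone (camera adjusted p = 0.000249; adjusted p = 0.549 with an estimated correlation), with MT-ND3 at 1.49 ± 0.18 and MT-CO3 at 1.18 ± 0.16. Heat shock proteins had 12 of 15 higher, 13 over the list alone (camera adjusted p = 1.08e-05; adjusted p = 0.549 with an estimated correlation), with HSPA8 at 0.89 ± 0.16 and HSP90AB1 at 0.80 ± 0.14. Mesenchymal glioblastoma markers had 10 of 22 higher and 2 lower, also over the list alone (camera adjusted p = 0.000267; adjusted p = 0.549 with an estimated correlation), with TIMP1 at 1.78 ± 0.18, vimentin VIM at 1.48 ± 0.19 and the galectin LGALS1 at 1.18 ± 0.14. With the sense-intronic share as a model term, the median went from 1.97 to 0.81 for histone genes, from 0.80 to 0.35 for ribosomal proteins and from 0.92 to 0.30 for oxidative stress genes. It went from 0.77 to 0.13 for heat shock proteins and from 0.27 to 0.07 for mesenchymal markers. It stayed near its value for DNA replication (0.50 and 0.43) and mitochondrially encoded genes (0.83 and 0.69). The mitochondrially encoded share of counts differed between the combination libraries, with 1.157% in replicate 1 and 0.815% in replicate 2. In the belinostat libraries it was 0.542% and 0.459%. Of these lists only heat shock proteins no longer passed camera (adjusted p = 0.45). Standard errors grew in that fit, and 16 histone genes, 2 ribosomal protein genes, 1 replication gene, 1 mitochondrial gene, 2 mesenchymal markers and 0 genes of the oxidative stress and heat shock lists were called higher.

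FOS and FOSB, immediate early genes, fell by 2.07 ± 0.27 and 2.31 ± 0.33, and EGR1 by 1.64 ± 0.25 (adjusted p = 0.000486). CCN1 fell by 0.64 ± 0.15 (adjusted p = 0.00528) and CCN2 by 0.64 ± 0.13 (0.00164). With the sense-intronic share as a model term FOS (-2.52, adjusted p = 6.85e-07), FOSB (-1.46, 0.0139) and EGR1 (-1.23, 0.0104) were still called. In that fit CCN1 was at -0.30 ± 0.23 (adjusted p = 0.745), while CCN2 kept its fold with a larger error (-0.67 ± 0.22, adjusted p = 0.203). Under the rule for named genes, the largest falls were of TNFSF14, a TNF family cytokine (-2.79 ± 0.38), GCGR, the glucagon receptor (-2.72 ± 0.69), SSPOP (-3.49 ± 0.46), ADAMTSL4-AS1 (-2.78 ± 0.56) and RN7SKP16 (-2.62 ± 0.43). With the sense-intronic share as a model term none of these 5 was called, and the direction was lost for SSPOP (0.01, adjusted p = 0.992) and GCGR (0.25, adjusted p = 0.963). SSPOP, ADAMTSL4-AS1 and RN7SKP16 are a pseudogene, an antisense gene and a copy of an abundant small RNA, and their counts are uncertain because the strand setting of the counting is not given in the sources used here. Of the genes named in advance, XRCC6 rose by 0.89 (adjusted p = 0.00112), CDKN1A by 0.86 (0.000783), XRCC5 by 0.82 (0.00125), PARP1 by 0.69 (0.00301) and PRKDC by 0.39 (0.0388), and HDAC6 fell by 0.95 (0.000581). All of these calls were lost with the sense-intronic share as a model term. There XRCC6 was at 0.10 (adjusted p = 0.91), CDKN1A at 0.38 (0.537) and XRCC5 at 0.14 (0.859). PARP1 was at 0.22 (0.788), PRKDC at 0.08 (0.938) and HDAC6 at -0.40 (0.544). Without that term HDAC3 was at -0.12 (0.446) and BRCA1 at 0.24 (0.142).

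**Figure D4:**
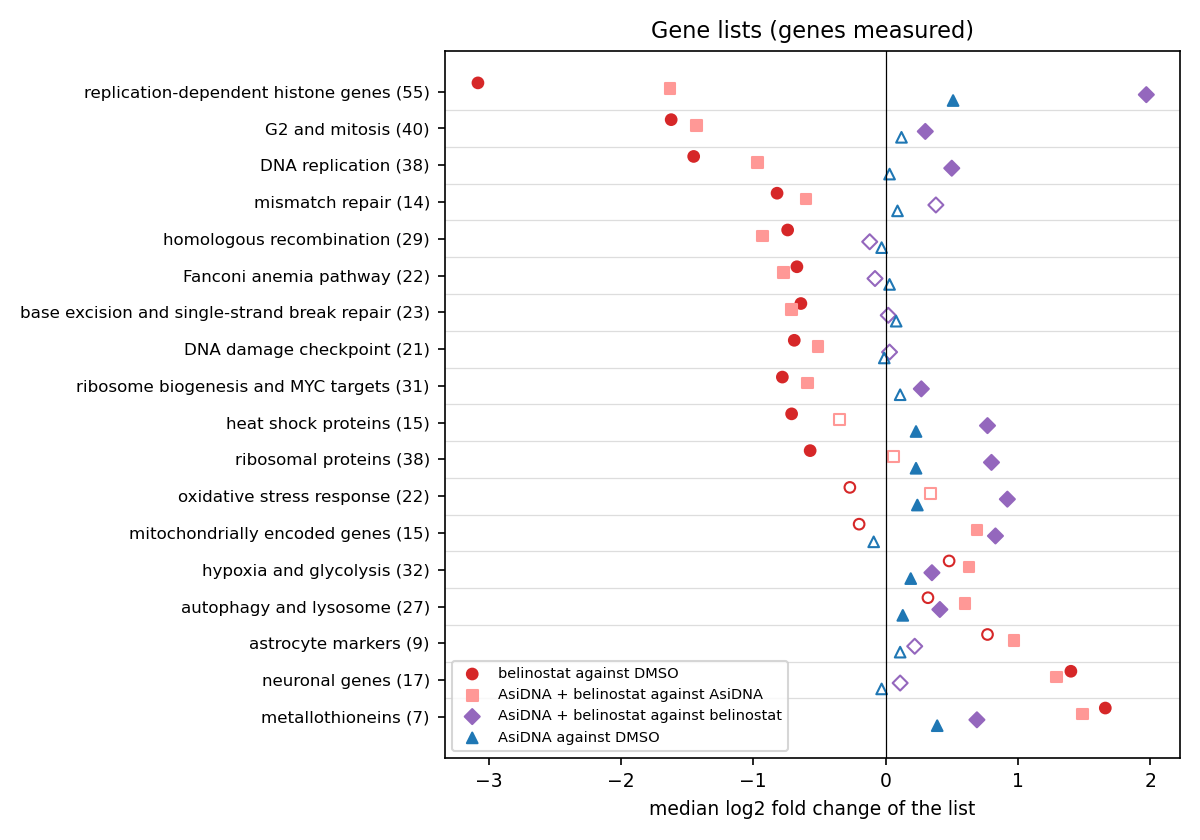
Median log2 fold change of 18 gene lists in 4 comparisons, with the number of genes measured in brackets; filled symbols mark a camera adjusted p under 0.05. Histone genes lie at -3.08 with belinostat against DMSO and at 1.97 in the combination against belinostat; with scaling by library size only, medians near 0 turn sign for ribosomal proteins in the combination against AsiDNA, for base excision repair and checkpoint genes in the combination against belinostat, and for the replication and Fanconi anemia lists in AsiDNA against DMSO; there the checkpoint median of -0.01 becomes 0 with RLE factors.

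Genes that differed between the combination and belinostat also differed between the DMSO replicates. Over 8142 genes with a mean log2 CPM above 4, the difference between the combination and belinostat correlated with the difference between DMSO replicate 2 and replicate 1 with r = -0.864, although these values share no library, and 94.7% of the 6398 called genes had opposite signs in them. For the difference between the AsiDNA replicates r was 0.052. The AsiDNA effects with and without belinostat correlated with r = 0.561, which became 0.025 without DMSO replicate 2 and 0.599 without DMSO replicate 1. The AsiDNA and belinostat effects, which share the DMSO libraries, had r = -0.132 and a covariance of -0.0869, against 0.456 and 0.0417 in 20 simulations of unchanged groups. These simulations drew each gene independently and held no belinostat effect. They lack the coordinated difference between the DMSO replicates and are therefore no baseline for the observed values. The observed r was 0.076 without DMSO replicate 1 and 0.291 without DMSO replicate 2. Part of such values comes from the shared controls.

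**Figure D5:**
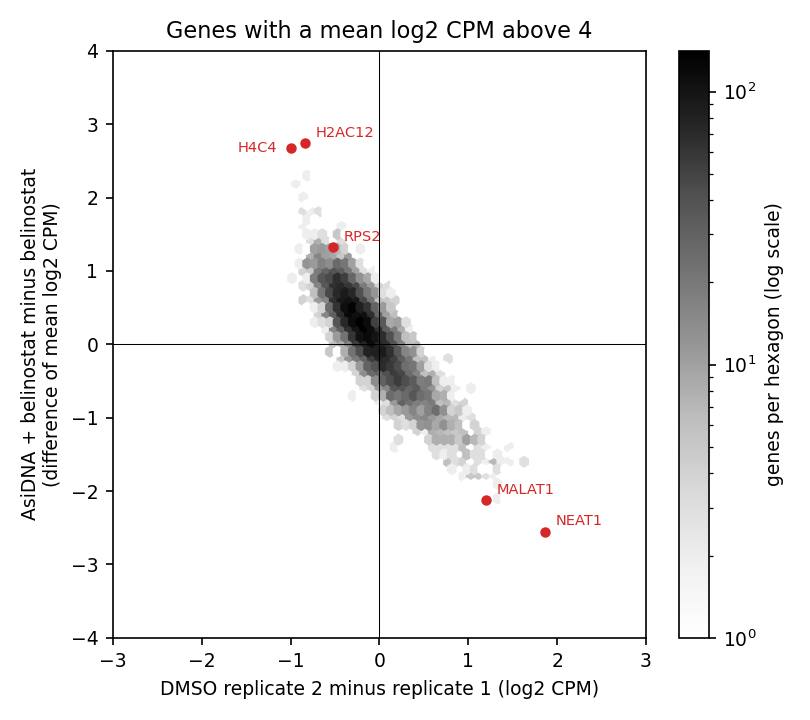
For 8142 genes, the log2 CPM difference between DMSO replicate 2 and replicate 1 (x axis) and between the combination and belinostat (y axis), shaded by the number of genes per hexagon, with named genes in red. The differences correlate with r = -0.864, with MALAT1 and NEAT1 at the lower right and the histone genes H4C4 and H2AC12 at the upper left.

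Against DMSO, the combination raised LOXL4 by 7.74, DACT3 by 6.25, LIVAR by 5.96 and SYP by 5.6 ± 0.20 on the log2 scale, and DNAI1 from 2 to 113 counts, a ratio of 82.5 (95% interval 22.3 to 690). Under the rule for named genes, the largest falls were of PLEKHG4B (-4.20), RPSAP52 (-3.85), HAS2 (-3.62), FAR2 (-3.60) and TNXB (-3.60), the last of which overlaps other genes and has a pseudogene copy. MT1X rose by 4.69 ± 0.20, the actin-severing gelsolin gene GSN by 2.38 ± 0.15, NDRG1 by 1.92 ± 0.15 and ATG9A by 1.15 ± 0.13, and MKI67 and KIF20A fell by 2.25 ± 0.13 and 2.03 ± 0.14. All 40 genes of G2 and mitosis were lower, also over the list alone (camera adjusted p = 1.04e-29; adjusted p = 0.215 with an estimated correlation). Of the histone genes 40 of 55 were lower and 1 higher, 42 and 1 over the list alone (camera adjusted p = 2.05e-07; adjusted p = 0.619 with an estimated correlation); without DMSO replicate 1 there were 31 lower and 7 higher. HDAC3 rose by 1.49, while BRCA1 fell by 1.33, PARP1 by 0.61 (adjusted p = 0.00352) and CDKN1A by 0.40 (0.0289). XRCC5 was at -0.35 (0.0731), PRKDC at -0.16 and XRCC6 at -0.05 (0.829), which became 0.28 without DMSO replicate 1 (adjusted p = 0.0124) and -0.30 without DMSO replicate 2 (adjusted p = 0.00539). In total 3586 genes were higher and 3498 lower, of which 1565 and 1677 by at least 2-fold.

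Whether the belinostat effect differed between AsiDNA cells and control cells was tested as an interaction. AAAS, which encodes a nuclear pore protein, was the 1 gene called: it lay at 35.7 ± 3.5 CPM in DMSO, 36.9 ± 2.5 in AsiDNA, 117 ± 0.17 in belinostat and 45 ± 2.1 in the combination, an interaction of -1.42 ± 0.19 on the log2 scale (adjusted p = 0.0439). It was called in 2 of 8 fits that left out 1 library, those without a DMSO library, and its adjusted p ranged from 9.74e-11 to 0.343. In edgeR's quasi-likelihood test 3203 genes had an unadjusted p under 0.05, and DESeq2 called 705. The count of 1 became 1020 without DMSO replicate 1 and 5358 without DMSO replicate 2, and 0 or 1 without any other single library. CDKN1A (0.72, adjusted p = 0.0903), PARP1 (0.59, 0.134) and HDAC3 (-0.24, 0.428) were not called.

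Among markers of other cell types, few of immune and epithelial cells were measured. Of 20 immune markers 3 had enough counts to be tested, the most abundant being TMEM119 at a mean of 35.5 CPM. Of 14 epithelial markers 2 were tested, with MUC1 at 2.20 CPM, and of 14 endothelial and pericyte markers 6 were tested, with PDGFRB at 104 CPM.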

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

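The tests of nuclear RNA content, the sense-intronic share, abundant RNAs, mixed RNA, gene length and the CCN1, CCN2 and EGR1 result were chosen after the result was seen; only the test of a weaker belinostat response was set before its result.

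AAAS is listed because the interaction term differed between cells with and without AsiDNA: its belinostat effect in AsiDNA cells minus that in control cells was -1.42 on the log2 scale. For 19 gene lists the interaction passed camera, which is why they are listed, while 0 passed with an estimated correlation or in fry and 9 with the sense-intronic share as a model term. Lost with that term, given as the interaction median without and with it and the adjusted p, were G2 and mitosis (0.20, 0.04, 0.802), heat shock proteins (0.50, 0.13, 0.521), hypoxia (0.24, 0.07, 0.673), HDAC inhibitor response (0.31, 0.06, 0.819) and matrix proteases (0.21, 0.07, 0.14). So were ribosome biogenesis (0.21, 0.08, 0.115), autophagy (0.27, 0.04, 0.313), TGF-beta and YAP targets (0.20, 0.06, 0.542), the amino acid response (0.47, 0.28, 0.141) and antigen presentation class I, whose median stayed near its value (0.22, 0.17, 0.103). Interaction medians also moved with the DMSO libraries. For TGF-beta and YAP targets the median was 0.05 without DMSO replicate 1 and 0.34 without DMSO replicate 2, and for heat shock proteins 0.29 and 0.73. No member of the 19 lists was called in the main fit. Without the term the camera adjusted p was 5.64e-38 for replication-dependent histone genes, 5.42e-17 for ribosomal proteins, 6.78e-09 for mitochondrially encoded genes, 8.78e-09 for oxidative stress response and 4.44e-08 for DNA replication. It was 0.00026 for mesenchymal glioblastoma markers, 0.00034 for heat shock proteins, 0.00375 for the unfolded protein response and for matrix proteases, and 0.00488 for the amino acid response and for senescence-associated genes. It was 0.0142 for inflammatory cytokines, 0.0175 for autophagy and lysosome, 0.0239 for ribosome biogenesis, 0.0291 for G2 and mitosis, for antigen presentation and for hypoxia, 0.034 for TGF-beta and YAP targets and 0.0343 for HDAC inhibitor response.

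Across genes, the combination differed from belinostat in the direction opposite to that from DMSO replicate 1 to DMSO replicate 2 (r = -0.864). A few abundant RNAs that took counts would move all other genes of a library by 1 common factor. The tables argue against this as the source of the pattern, since the called genes went both ways. Of them 3237 were higher and 3161 lower in the combination, with a median absolute log2 fold change of 0.821. Without the 10 most abundant genes 95.1% of the calls were made again in the same direction. That repeat decides nothing, since the TMM factors of both fits already offset the share of such genes, so few calls could be lost. Varying nuclear or incompletely spliced RNA cannot be told apart from other sources of this pattern, since the r is the pattern itself and tests nothing further. With the sense-intronic share as a model term the median signed log2 fold change of the called genes went from 0.821 to 0.224, which is 27.3% of its value, the median standard error of single genes went from 0.178 to 0.251, and calls went from 6398 to 85; that share differs between the DMSO replicates too, so the fit draws on the same difference, and a share that treatment itself alters would be removed by the same term. A weaker belinostat response in AsiDNA cells cannot be told apart from this. In its test a belinostat library minus 1 AsiDNA library was fitted on a combination library minus the other AsiDNA library. The difference between DMSO replicate 2 and replicate 1 was a second term. A weaker response gives a slope above 1 in this fit, unlike the slope of 0.691 given earlier, which runs the other way and uses DMSO. The slope of 1.021 (0.975 to 1.063 over 8 choices of libraries) lay below the 1.2 that the test required for a weaker response. Its upper end narrowly passed the bound set against it.

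DMSO replicate 2 lay between DMSO replicate 1 and the belinostat libraries on the first principal component and in its MALAT1 and NEAT1, sense-intronic and histone shares, but beyond them on the second component (52.4, against 2.7 and 23.2 to 34.0). The tables argue against belinostat RNA mixed into it as the whole cause: 17 genes expressed only with belinostat reached 2.53% of their belinostat level (1.86 to 3.29), where MALAT1 would need 9.35% and NEAT1 19.48%. They also argue against gene length, since r with the combination minus belinostat stayed at -0.791 after a fit on exon length. Differences in handling or culture density were not tested and stay open, and no biological explanation was tested because both libraries carry the same label.

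CCN1, CCN2 and EGR1 were lower with AsiDNA. The tables argue against 1 deviating DMSO library as the source of these falls, since their size was similar against either library. Without DMSO replicate 1 the log2 fold changes were -1.16 (CCN1), -1.18 (CCN2) and -1.87 (EGR1). Without DMSO replicate 2 they were -1.05, -1.27 and -1.57. That the genes stayed called in these fits decides nothing, since each fit leaves out the spread between the DMSO replicates. The tables also argue against chance in the 4 libraries compared, since 3 of the 3 were lower in the combination against belinostat, which uses 4 other libraries. In that comparison 3161 of 14741 genes were lower, and 0.6 of the 3 would be for independent lists. This is weaker than it looks where that comparison follows the difference between the DMSO replicates: with the sense-intronic share as a model term it gave -1.23 for EGR1 (adjusted p = 0.0104), -0.67 for CCN2 (0.203) and -0.30 for CCN1 (0.745). An effect of AsiDNA stays open as a hypothesis found and tested on the same data, and culture density, to which these genes are known to respond, was not tested.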

How the results depend on the processing

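The sense-intronic model term, the fit without the 10 most abundant genes and the fit of protein-coding genes only were chosen after seeing the data. Of 284 values of named genes, RLE factors kept 282 on their side of the threshold, DESeq2 272 of 283, library size only 269 and the sense-intronic term 239; leaving out libraries kept 2170 of 2272. Of 276 list results the estimated correlation kept 170, fry 193 and the sense-intronic term 227. A lone library left in a group is assumed to vary like the other groups. Depth limits ratios of genes with few counts.

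For belinostat against DMSO a 2-fold limit gave 4470 genes and glmTreat 4452; for the combination against DMSO these were 3242 and 3122, and for the combination against AsiDNA 2772 and 2560 (leaving out libraries, 4102 to 8247). For the combination against belinostat an adjusted p under 0.01 gave 3804, a 2-fold limit 2285, glmTreat 1479, the sense-intronic term 85 and leaving out libraries 3142 to 8477. For AsiDNA against DMSO an adjusted p under 0.01, glmTreat and only the groups compared gave 0, library size only 1, no filter 520, DESeq2 32, the sense-intronic term 47 and leaving out libraries 0 to 4955. The interaction gave 0 at an adjusted p under 0.01 and with glmTreat, 10 with RLE factors, 157 with library size only, 1549 with no filter, 351 with 1 CPM in 2 libraries, 705 with DESeq2, 238 with the sense-intronic term, 386 without the 10 most abundant genes, 3 with protein-coding genes only and 0 to 5358 leaving out libraries. Stricter limits lower counts by construction. Leaving out a DMSO library takes the DMSO pair out of the estimate of spread that all groups share. Log2 differences in that pair had the largest SD (0.377, against 0.145 to 0.194 in the other groups). The lone DMSO library is then assumed to vary like the other groups, which by construction favors higher counts. Otherwise the cause was not tested.

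The labels share only replicate numbers between groups, and deviations of libraries with the same number correlated with r from -0.196 to 0.139. A replicate block gave 5 genes for AsiDNA against DMSO and 19 for the interaction; the counts of the other comparisons stayed within 1.5 times.

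Leaving out libraries, the agreement of the belinostat effects ranged from 0.679 to 0.783, that of the AsiDNA effects from 0.025 to 0.599, and that of AsiDNA with belinostat from -0.153 to 0.291, turning sign without DMSO replicate 1 (0.076) and replicate 2 (0.291). XRCC6 in the combination against DMSO was called lower without DMSO replicate 2 (-0.302) and higher without DMSO replicate 1 (0.275). With the sense-intronic term SSPOP (0.006), GCGR (0.247) and NEAT1 (0.154) turned sign in the combination against belinostat. The cause was not tested.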

Other observations

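No test of an explanation is reported in this part, and SNORD3A was chosen after its values were seen.

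Cytokine genes moved in both directions with belinostat. Against DMSO, CSF3 fell by 3.87 ± 0.17 and IL11 by 3.56 ± 0.17 on the log2 scale, IL1B fell by 1.58 ± 0.13, and the chemokine CCL20 rose by 3.72 ± 0.22. Of 25 inflammatory genes 11 were lower and 6 higher, 12 and 6 over the list alone (camera adjusted p = 0.138). In AsiDNA cells CSF3 was at -3.09 ± 0.16, IL11 at -2.79 ± 0.17 and CCL20 at 4.35 ± 0.26. Interferon-stimulated genes were also mixed, with 16 of 31 lower and 7 higher, also over the list alone (camera adjusted p = 0.338): OAS3 fell by 3.01 ± 0.33 and DDX60 by 2.14 ± 0.27, while IFI6 rose by 1.84 ± 0.22 and STAT2 by 1.62 ± 0.16.

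Genes of the amino acid response had 15 of 20 lower and 3 higher with belinostat against DMSO, also over the list alone (camera adjusted p = 0.0117; adjusted p = 0.478 with an estimated correlation and 0.0957 with the sense-intronic share as a model term, where 12 were lower and the median went from -0.71 to -0.57), among them the transcription factor ATF5 (-2.88 ± 0.29) and the folate enzyme MTHFD2 (-1.09 ± 0.14). CCN2 rose by 2.46 ± 0.13 and TGFB2 by 2.03 ± 0.16 in the same comparison.

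SNORD3A, a small nucleolar RNA, had 1307 counts in belinostat replicate 1. In the other libraries it had 17 and 10 (DMSO), 11 and 14 (AsiDNA), 4 (belinostat replicate 2), and 4 and 6 (combination). The quasi-likelihood test called SNORD3A for belinostat against DMSO (5.86 ± 1.3, adjusted p = 0.00156). It also called SNORD3A for the combination against belinostat (-6.73 ± 1.5, adjusted p = 0.00342). Both calls rest on belinostat replicate 1, so the totals of called genes can hold genes that were high in 1 library.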
